A study of Solanum tuberosum with 289 samples.

How the data were processed

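RNA was taken from leaflets of field-grown potato plants, pooled over the plants of each plot, and sequenced as short tags on an Illumina Genome Analyzer II, per the labels' protocols. Each of the 289 libraries stands for 1 plot. The labels give the clone, the run, the channel and the barcode of each library, and the series design states that the 3 runs, A, B and C, each pooled 1 field block, so that run and block cannot be separated. Libraries were grouped by clone id into 91 clones of the diploid family 15143, its 2 parental clones and 6 tetraploid varieties. The class label of 4 libraries disagreed with their clone id, and the clone id was used.

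The files deposited by the authors hold whole-number counts per tag of 17 bases, without a header and without normalization. How the tags were cut from the reads, and with which tools and filters, is not given in the sources used here. Each library has a full tag list, which was used as the main file, and a shorter list whose tags form a set of 100494 over the series, of which 100410 were seen in at least 3 libraries of 1 clone. In 287 libraries the short list repeats the counts of the full list, and in the other 2 it holds the counts of another library and was not used. The full lists hold 29321084 distinct tags and 267710398 counts, and 82.6% of the tags were seen in 1 library only. Tags with a series total of at least 20, which are 611613 tags with 83.3% of the counts, were kept for all steps, and library sizes were the totals of the full lists.

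Of the kept tags, 55.5% lie 1 base away from a tag with at least 20 times their total. Such a tag can be another allele or a copying error of its neighbour, and is called a 1-base neighbour. Tags 2 bases away from such a tag were not treated as neighbours. A difference in a tag between genotypes can be one of tag sequence as well as of transcript level, and these were not told apart. No transcript or genome sequence was used here, so tags were not matched to genes. The gene lists and the correlations with StCDF1, a potato gene of the maturity pathway, that had been planned before the data were examined were therefore not computed. Among the 20000 most abundant tags 0.415% hold the 4-base site CATG, against 4.90% with GATC and 5.49% with TGCA.

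Differential abundance was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization and Benjamini-Hochberg adjustment, and a tag was called at an adjusted p below 0.05. The varieties and the 15143 clones were compared on counts summed over the libraries of each genotype, so that a genotype is 1 replicate. The other comparisons used single libraries with a term for each clone and a term for the run as block, because each run pooled 1 field block per the series design, while replicate numbers do not always follow the blocks. The parental contrast and the contrast of the family mean with the midparent were fitted over all libraries, which share 1 estimate of the spread between plots. Low tags were removed with filterByExpr for the comparisons of classes, parents and varieties. For the comparisons among clones and with the midparent, tags needed a mean of at least 10 counts per library, a filter set after the data were examined. Fits with a term per clone were solved by a routine written for this layout, with the dispersion trend from a seeded sample of 1000 tags. Against edgeR's own functions its −log10 p differed by at most 2.13e-06 over 200 tags.

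Standard errors of log2 fold changes were taken as the fold change over the square root of F and are approximate. In the parental and midparent contrasts a clone without counts entered the fold change with 0.5 counts. Where a group had no count, the fold is given as a lower bound against 3 counts over the group, and with 1 count as a ratio of pooled CPM with an exact Clopper-Pearson interval of 95%. These limits cover counting error only. Levels are TMM-normalised counts scaled to a common library size (counts per 1e6, CPM). Repeatability is the share of the variance of log2 CPM, with a prior count of 1, that lies between clones after run means were removed. Without gene names the rule fixed for naming genes could not be applied, so the tags named are the 2 called tags with the smallest p in each direction, or the 2 with the smallest p where the test has no direction.

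The tests were tried on simulated data, with 2000 tags of which 200 were changed and a dispersion of 1. The test of varieties against clones recovered 100% of 4-fold changes, and that among clones 97%. In the simulated comparison of varieties with clones, all genotypes of a class shared 1 mean, without differences between them. Its counts were summed over plots, with a lower dispersion for a sum. The 100% can therefore overstate the recovery in the real data. The midparent test recovered 52% of 4-fold changes and 100% of 16-fold changes, and 5% of its calls were false. The parental test recovered 1% of 4-fold and 4% of 16-fold changes, and the test among varieties 1% and 25%.

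Similarity between libraries was the Pearson correlation of log2 CPM over the 2000 most variable tags, after run means were removed. No pair of libraries of 1 genotype agreed within sampling noise, since the lowest chi-square per tag was 10.98. A library was set apart when its best correlation with its own clone was under 0.1, or, in the family, when it held, at 5 CPM or more, over 10% of the 599 tags that were abundant in a variety and absent from both parents. This applied to 13 libraries, which were kept in all main results. Parental tags were those with at least 20 CPM, counts in each of the 3 plots of 1 parent and no count in the other, without 1-base neighbours. Such a tag counted as found in a clone or library at 0.1 or more of its level in the parent, and a tag of Green Mountain at 0.1 or more of its level in Green Mountain.

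Alternatives fixed before the data were examined were RLE size factors, the short tag lists, DESeq2 1.42.0 or limma voom (limma 3.58.1) in place of edgeR, fits without the run, fits of the 6 parental libraries alone, single runs, and each variety, parental library or run left out in turn. Alternatives chosen after the data were examined were other count filters, tags without 1-base neighbours, the family without the libraries set apart, and the family as 1 term on clone sums. A fit without any count filter, tags matched to genes with 1 mismatch, and all alternatives of the gene lists were not run. No library had under 10% of the median total, so none was left out for depth. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the summaries and plots.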

Results

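Leaf transcripts of a diploid potato mapping family, of its parents and of tetraploid varieties were counted as sequence tags of 17 bases in 289 libraries, each from 1 field plot. The series concerns resistance to Verticillium dahliae, a soil fungus that causes wilt, and the pathway that sets maturity and tuber formation. The family, 15143, was represented by 91 clones in 262 libraries, and its parental clones 07506-01 and 12120-03 by 3 libraries each. The tetraploid varieties Atlantic-1, Green Mountain, Hindenburg, Kennebec, Russet Burbank and Shepody were represented by 21 libraries, 6 of them from Green Mountain. Most genotypes, 88 of 99, had 3 libraries, and 77 of them had 1 library in each of the 3 blocks. Total counts per library ranged from 120642 to 2210849 with a median of 921150, and the median number of distinct tags was 220903. The labels used here carry no score for maturity, tubers or disease, so no tag was set against a trait. Tags are named by their sequence, because no transcripts were used to assign them to genes.

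Plots of 1 genotype resembled each other in the levels of their tags. Of the 288 libraries with a second library of their genotype, 266 were most similar to a library of that genotype, against at most 13 when clone labels were shuffled within runs 1000 times. The median correlation was 0.322 between plots of 1 genotype and -0.00844 between genotypes. The presence of abundant tags nevertheless differed between plots of 1 genotype. Of the tags with at least 50 counts in 1 plot, a median of 22.3% had no count in another plot of the same genotype, where counting error alone allowed at most 0.0366%. Differences between plots and losses in library making are not separated by this share, which was 23.8% in the family, 16.1% in the parents and 9.80% in the varieties.

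The parents were compared to find tags that could differ in the family. At 208 of 8236 tags tested the abundance differed between the parents, 137 being higher in 07506-01 and 71 higher in 12120-03. Without 1-base neighbours of abundant tags these were 78 and 61 tags, of which 34 had no count in 12120-03 and 27 had none in 07506-01. Of the 78 tags, 11 lie 2 bases from AGAACTAATAATAGTAA, which reached 17134 ± 5360 CPM in 07506-01 (SD, n = 3 plots) and was called itself. Copying errors of that tag are not excluded among these 11. The tag TGCTAAAAAAAAAAAAA reached 1421 ± 709 CPM in 07506-01 (SD, n = 3 plots) and 38.8 ± 10.2 CPM in 12120-03, a log2 difference of 5.14 (SE 0.595, edgeR adjusted p = 1.79e-11). TTGCCATAAAAAAAAAA reached 915 ± 490 CPM in 07506-01 and 10.1 ± 8.86 CPM in 12120-03, a log2 difference of 6.33 (SE 0.779, edgeR adjusted p = 1.46e-10). In the opposite direction, AGCTAAAAAAAAAAAAA, which is 1 base apart from TGCTAAAAAAAAAAAAA, stood at 22.0 ± 10.3 CPM in 07506-01 and at 1146 ± 779 CPM in 12120-03, a log2 difference of -5.50 (SE 0.674, edgeR adjusted p = 1.46e-10). The 2 tags that are 1 base apart can be alleles of 1 transcript, which was not tested. TAATCGCTCTTTCACTT had 1 count in 07506-01 and 1908 counts in 12120-03, 576 ± 267 CPM, a ratio of pooled levels of 1393 with an exact 95% interval from 250 to 55056 (edgeR adjusted p = 2.85e-09). For each of these tags the 3 plots of one parent lay above the 3 plots of the other, and each was found in all 91 clones, with family means of 605, 458, 339 and 200 CPM. Leaving out single plots of 12120-03 lowered the number of calls most, to 111 without replicate 1 and to 99 without replicate 2. The 6 parental libraries fitted alone gave 0 calls with edgeR, with 798 tags at an unadjusted p below 0.05, and 778 calls with DESeq2.

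Among the 15143 clones, 2493 of 9471 tags differed in abundance between clones beyond the spread between plots, in 261 libraries of 90 clones with the block in the fit. Of the 8316 tags that were no 1-base neighbours, 25.4% differed. The largest evidence was for GTATTGGAAAACTGATA, whose clone means ran from 16.5 to 2984 CPM (edgeR F test, adjusted p = 9.13e-58) with a repeatability of 0.920. In 42 clones it stood at 113 CPM or lower and in the other 48 at 322 CPM or higher. The lowest 3 of the 48, 15143-84 at 322 CPM, 15143-29 at 323 CPM and 15143-83 at 516 CPM, include libraries set apart for doubtful identity, as does 15143-02 at 2984 CPM, and the next clone above them, 15143-46, stood at 1343 CPM. Of the parents, 07506-01 had 2372 CPM and 12120-03 had 113 CPM. GATCCTATTAAATTTTC showed the opposite parental levels, 46.0 CPM in 07506-01 and about 2.2e+03 CPM in 12120-03. Its clone means ran from 11.2 to 2489 CPM (edgeR F test, adjusted p = 9.28e-50, repeatability 0.862), with 53 clones at 149 CPM or lower and 37 at 342 CPM or higher. Of the clones next to this gap, 15143-38 at 137 CPM, 15143-02 at 146 CPM and 15143-15 at 570 CPM include libraries set apart. The median repeatability was 0.0752 over the 8316 tags and 0.357 over the called ones. A repeatability above 0.5 was reached by 562 of the 8316 tags, against 0 when clone labels were shuffled. Of the called tags that were no neighbours, 888 were found in 30 to 70% of the clones and 144 in all of them. In a seeded sample of 2000 of the tested tags 533 were called, against at most 41 with clone labels shuffled within runs. With 1 run left out the number of calls was between 1343 and 1417.

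**Figure D1:**
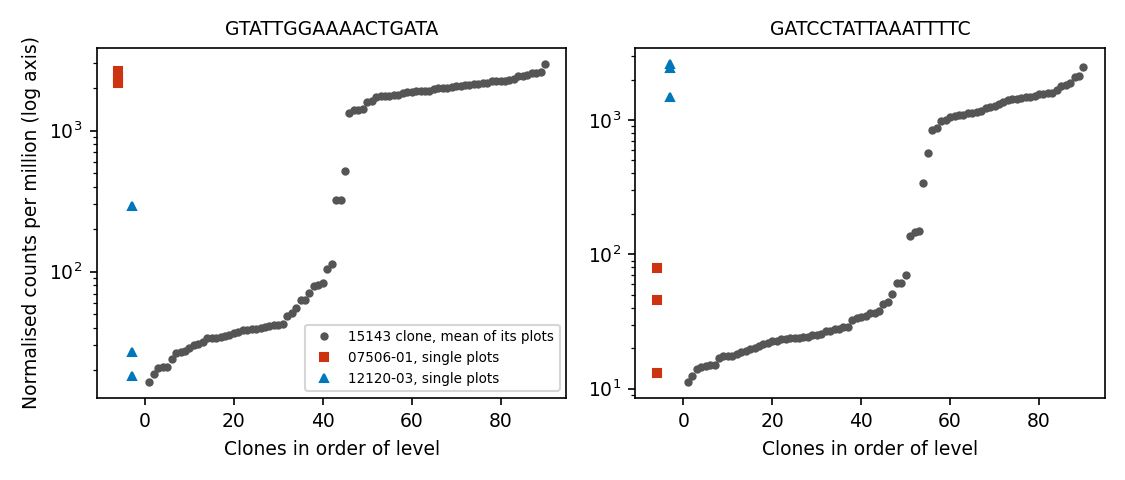
Normalised levels in CPM on a log axis for the 2 tags with the smallest p among the 15143 clones, with each grey point the mean over the plots of 1 of 90 clones in order of level, and coloured points the single plots of the parents. The clones fall into a low and a high part, 42 and 48 clones for GTATTGGAAAACTGATA and 53 and 37 clones for GATCCTATTAAATTTTC.

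Tags found in only one parent were followed through the family. In total 209 tags with at least 20 CPM were found in every plot of 07506-01 and in none of 12120-03, and 159 tags the other way round. Of these, 153 and 120 entered the test between the parents, and 31 and 27 were called. Abundant tags were also absent from single plots of 1 genotype, so some of the 209 and 159 tags may not be particular to 1 parent. Of the 209 and 159 tags, 107 and 98 were found in 35 to 65% of the 90 clones, and 20 and 20 in at least 90%. Among 1250 tags at similar levels in both parents, 86.4% were found in at least 90% of the clones and 0.96% in 35 to 65%. Of the parental tags in 30 to 70% of the clones, 84 of 07506-01 and 77 of 12120-03 were abundant enough for the test among clones, and 79 and 75 of them passed it. These tags were picked by their presence in the same clones, so passing this test is no separate evidence. Of the tags called between the parents, without neighbours, 132 were tested among clones and 97 passed, against 20.4% of the 5714 tags tested in both comparisons. Both tests take their spread between plots mostly from the family, so a tag with a small spread passes both more easily. The higher share is therefore no separate evidence of inheritance.

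**Figure D2:**
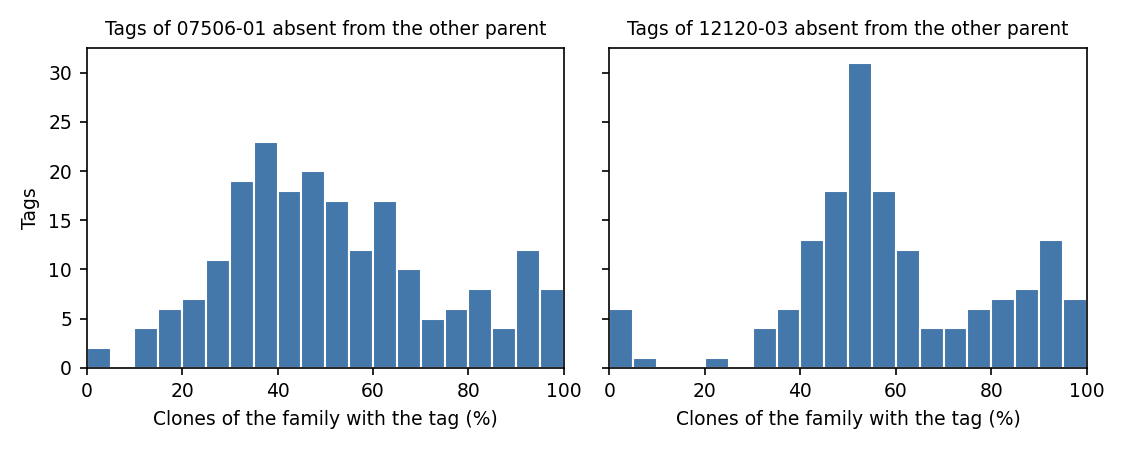
Number of tags found in 1 parent only, by the percentage of the 90 clones of the family in which they were found, for 209 tags of 07506-01 (left) and 159 tags of 12120-03 (right). Of these, 107 and 98 tags lie between 35 and 65% of the clones.

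The family mean was compared with the midparent, which asks whether tag levels in the clones centre between the parents. The model averages log levels with each clone as a term. It gave 1105 of 9471 tags, 26 with a family mean above the midparent and 1079 below. Chance is not excluded for this number, because in a sample of 250 tags 8 of 60 pairs of clones put in the place of the parents, the real pair included, gave at least the 30 calls of the parents. On the CPM scale the picture was different for part of these tags. Of the 996 tags below without neighbours, 189 had a family mean in CPM above the midparent in CPM, and of the 22 tags above without neighbours 7 had one. The median number of clones with counts was 68 of 91 over the 996 tags, against 85 for tags not called. With the family as 1 term on clone sums, 43 tags were called, 24 above and 19 below. TATTTTGCCTAATGTCA averaged 70.9 CPM over the family (SD 101, n = 91 clones) against a midparent of 189 CPM (edgeR adjusted p = 3.62e-20), with counts in 83 clones and 10 clones above the midparent. TATTTTGCCTAAAAAAA averaged 12.2 CPM (SD 18.1, n = 91 clones) against 46.0 CPM (edgeR adjusted p = 5.24e-16), with counts in 58 clones and 7 above the midparent. Neither tag was called with the family as 1 term. The sequences of both start with the same bases, so they may stand for 1 transcript and may not be 2 separate findings. Of the tags above, TTGCCATAAAAAAAAAA had a family mean of 458 CPM against a midparent of 463 CPM, and TAATCGCTCTTTCACTT 200 CPM against 288 CPM, with 39 and 17 clones above the midparent. These 2 tags differ strongly between the parents, and the mean of their parental log levels lies far below the mean of their parental CPM. Over all tags tested the median log2 difference between family and midparent was -0.369 with TMM. The split of 26 above and 1079 below includes this offset of all tags. RLE size factors moved the median by 0.205. The number of calls fell to 580 without 12120-03 replicate 2, the lowest of the 6 fits that leave out a parental plot.

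The tetraploid varieties were compared with the diploid clones, with ploidy and breeding pool changing together. At 1592 of 72435 tags the abundance differed, 1165 being higher in the varieties and 427 lower. Without 1-base neighbours these were 757 and 247 tags. Of the 757 higher tags, 326 had counts in all 6 varieties, 457 had no count in either parent, and 394 were seen in fewer than 10 of the 83 clones with no library set apart for doubtful identity. Of the 247 lower tags, 99 had no count in any variety. CGTTTAACTTAACGTTA had 254 counts in the varieties, 15.5 ± 5.81 CPM (SD, n = 6 varieties), and 1 count in the family, a ratio of pooled levels of 2764 with an exact 95% interval from 492 to 109620 (edgeR adjusted p = 5.22e-43). It was found in all 6 varieties but in 11 of their 21 plots, and had no count in the parents. GATCCGTATCATTGGAT, a 1-base neighbour, averaged 215 ± 300 CPM over the varieties and 16.4 ± 5.19 CPM over the 91 clones, a log2 difference of 3.70 (SE 0.205, edgeR adjusted p = 1.37e-28). Its level was 433 CPM in Hindenburg and 732 CPM in Kennebec, and 23.3 to 36.2 CPM in the other 4 varieties. The SE and p in this comparison come from 1 estimate of the spread over all genotypes, most of them clones. They reflect mainly the spread among clones and can overstate the precision for the 6 varieties. CGATTGTGCTACTCTAT averaged 2.16 ± 4.47 CPM in the varieties and 123 ± 54.3 CPM in the clones, a log2 difference of -5.83 (SE 0.691, edgeR adjusted p = 2.51e-10), with all 6 varieties below the median clone. It was found in 90 of 91 clones and in 12120-03, with 617 counts, and had no count in 07506-01. Its 1-base neighbour CGATTGTGCTACTCTCT had 817 counts in the family and 0 in the varieties, at least 25.0-fold higher in the family by counting error alone (edgeR adjusted p = 2.76e-10). The neighbour had 16 counts in 12120-03 and 0 in 07506-01, so it followed the more abundant tag. A copying error of that tag is not excluded, and the neighbour is then no separate result. Single runs gave 412, 269 and 343 calls for runs A, B and C. The median log2 difference of all tags was -0.233 with TMM, and RLE size factors moved it by -0.218. The split became 849 higher and 527 lower with RLE, and 395 higher and 2383 lower with DESeq2.

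Green Mountain held 106 tags of at least 20 CPM that were absent from both parents. Over the summed plots of each clone, the median clone of the family had 1.89% of these tags. The libraries labelled 15143-02 had 98.1% of them, those labelled 15143-38 had 84.0% and those labelled 15143-29 had 64.2%, and no other clone had more than 6.60%. Of 78 parental tags absent from Green Mountain, 15143-02 had 2.56%, 15143-38 had 0% and 15143-29 had 42.3%, against a median of 44.9% over the clones besides 15143-02 and 15143-38.

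**Figure D3:**
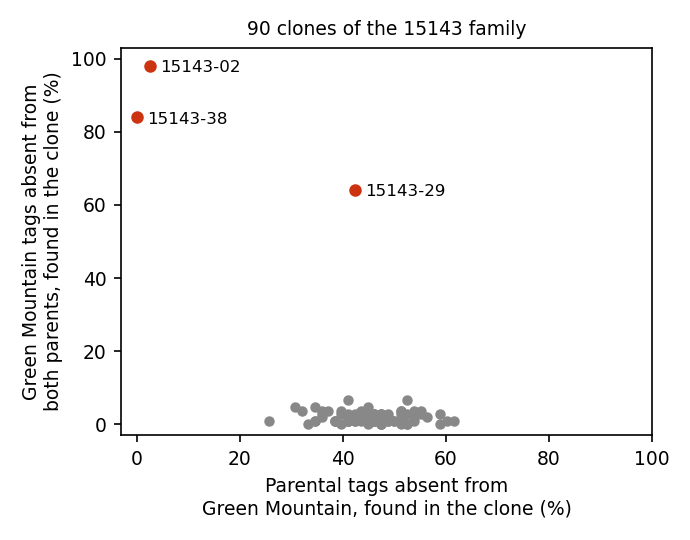
Percentage of 106 Green Mountain tags absent from both parents (vertical axis) against the percentage of 78 parental tags absent from Green Mountain (horizontal axis) found in each of 90 clones of the family, over the summed plots of the clone. The 3 clones in red are 15143-02, 15143-38 and 15143-29, with 98.1%, 84.0% and 64.2% of the Green Mountain tags, and no other clone has more than 6.60%.

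Among the 6 varieties, 395 of 24074 tags differed in abundance, of which 288 were no 1-base neighbours. Of these, 74 had counts in every plot of some varieties and in no plot of all others, 5 of them in 1 variety only. GGTCAGAATCATTGGAT reached 2039 ± 940 CPM in Atlantic-1 (SD, n = 3 plots) and between 24.0 CPM in Hindenburg and 56.1 CPM in Kennebec in the other varieties (edgeR F test, adjusted p = 1.43e-07). TAATGCCATTTTGTGAT was abundant in 3 varieties, with 660 ± 298 CPM in Atlantic-1, 609 ± 103 CPM in Shepody (SD, n = 3 plots each) and 636 ± 41.1 CPM in Green Mountain (SD, n = 6 plots), and had 9.88 CPM in Hindenburg, 11.9 CPM in Kennebec and 16.7 CPM in Russet Burbank (edgeR F test, adjusted p = 1.05e-06). In the family these tags had pooled levels of 41.9 and 24.0 CPM. Both are 1-base neighbours of more abundant tags. The number of calls depended on the runs, with 144 calls without run B and 1483 without run C.

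**Figure D4:**
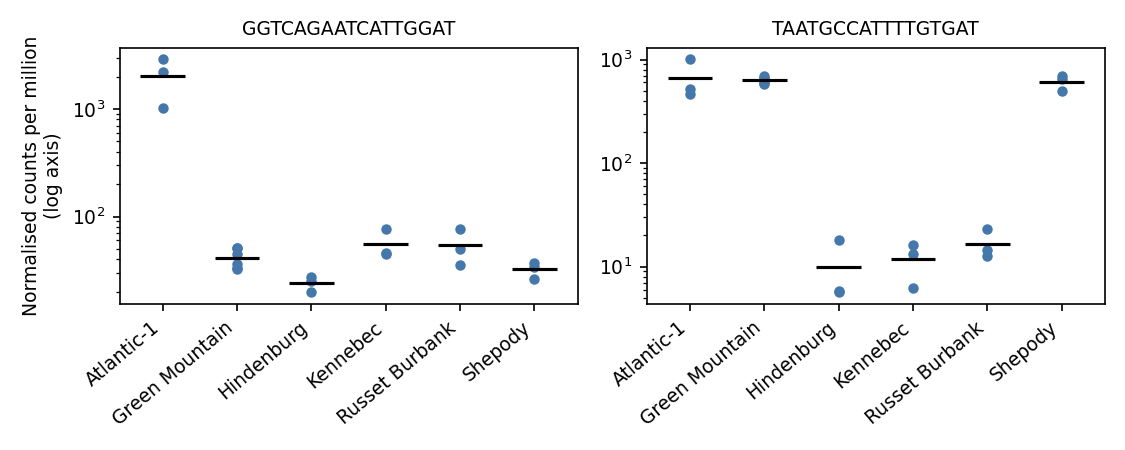
Normalised levels in CPM on a log axis for the 2 tags with the smallest p among the varieties, with each point 1 plot and each bar the mean of a variety. GGTCAGAATCATTGGAT is high in Atlantic-1 only, and TAATGCCATTTTGTGAT is high in Atlantic-1, Green Mountain and Shepody.

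Counts of 0 limit levels differently in these groups. Over the 21 libraries of the varieties 0 counts allow up to 0.137 CPM, over the 3 plots of 07506-01 up to 1.08 CPM and over those of 12120-03 up to 0.789 CPM, each from 3 counts of the summed totals. These bounds cover counting error only. Absence of abundant tags from single plots went beyond it, with a median of 22.3% between plots of 1 genotype, so true levels can be higher.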

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

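All tests of explanations in this part were chosen after the results were seen.

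The tag CGATTGTGCTACTCTAT stood at 11.01 CPM on average in Atlantic-1, while the next variety had 0.558 CPM, a gap of 0.9493 of the whole range over the 6 varieties which is beyond the limit of the outlier test. Of 10 sets of 6 values tested this way 1 was beyond the limit, and chance puts about 1 in 20 beyond it.

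The libraries labelled 15143-02 and 15143-38 carried Green Mountain tags and hardly any of the parental tags that Green Mountain lacks. Crosstalk between barcodes of 1 channel is argued against, because the 61 family libraries under other labels that share a channel with Green Mountain had at most 16.0% of its 106 tags, counted as found at 0.1 or more of their level in Green Mountain. Of the 6 libraries under the 2 labels, 4 were in channels without Green Mountain, and these had 52.8 to 92.5% of the tags. A mixture of the labelled clones with Green Mountain is argued against as well, since the higher of the 2 shares of parental tags was 2.56%, while the lowest among the 88 other clones was 25.6%. What stays open is that Green Mountain or a near relative grew in, or was sampled from, the plots under these 2 labels, for which the lower share of Green Mountain tags was 84.0%. No biological explanation was tested, because the labels give none.

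In 15143-29 the Green Mountain tags stood in block 3 only, with 67.9% of them found there by the same rule against 0% and 0.943% in blocks 1 and 2. That library kept 26.9% of the parental tags that Green Mountain lacks, so a mixture of the clone with Green Mountain, in the plot or in the tube, is a candidate explanation for it.

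Of the libraries of 15143-41 and 15143-98, the second of the former and the third of the latter resembled the other clone. Both come from block 1 and carry the barcode CCT in channels 1 and 2. Over 239 parental tags, their calls of presence were equal to those of the other clone's remaining libraries, the pair of these 2 libraries left out, in at least 75.3% of tags and to those of their own clone in at most 62.8%, where pairs of 1 clone had a 5th percentile of 66.5%. Low depth is argued against, since the lower of their best correlations with a library of another clone was 0.304, close to the median of 0.322 within genotypes. An exchange of these 2 libraries may explain this, and no biological explanation was tested.

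One abundant tag, with 681517 counts, made up 33.4% of the counts of 12120-03 in block 1 (Wilson 95% interval 33.3 to 33.5), 8.82% in block 2 (8.78 to 8.86) and 10.8% in block 3 (10.7 to 10.8). These intervals cover counting error only. It made up 3.08% in 07506-01 in block 1 (3.04 to 3.12), but had 32 and 0 counts in the other plots of that parent, and its sequence is not printed because its organism is not known. Inheritance from a parent is argued against, because 14 clones had over 100 counts in some plot and 0 clones had them in each plot. Crosstalk within a channel is argued against as the whole explanation, because 5 family libraries with over 100 counts had no other library of over 10000 counts in their channel. It may explain part of the counts. Of the 10 family libraries with over 100 and up to 10000 counts, 8 shared a channel with a library of over 10000 counts, against 29.6% of the 270 libraries with 100 counts or fewer (binomial p = 0.00145), and 71.2% of those low libraries had a count in channels with such a library and 22.1% elsewhere. The binomial test takes the libraries as independent, although some of the 8 shared a channel with each other, so its p may be too small. Why the tag is abundant in all 3 plots of 12120-03 and in part of the plots of other genotypes stays open, and a transcript of a microbe or virus was not tested.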

How the results depend on the processing

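Alternatives chosen after the data were examined are marked as added, and all tests with regrouped samples were chosen after the results were seen. The called tags were 1592 for the varieties against the clones, 208 between the parents, 2493 among the clones, 395 among the varieties and 1105 against the midparent. The causes of the changes below were not tested, except where fewer libraries or tags entered.

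For the varieties against the clones, DESeq2 called 2778 tags, of which 776 were shared, runs A, B and C alone called 412, 269 and 343, and limma voom on single libraries with the run as block called 7239. Tags without 1-base neighbours (added) gave 900 calls, and tags with a mean of 10 counts per library (added) gave 579, with 294 higher and 285 lower. Leaving out each variety gave 1248 to 1638. Between the parents, the fit of the 6 libraries alone called 0 tags, DESeq2 on them called 778, tags without neighbours (added) gave 111, and leaving out each plot gave 99 to 184. Among the clones, limma voom called 5719 tags, a mean of 5 counts per library (added) gave 6840, and leaving out each run gave 1343 to 1417. The count of 6840 is not reliable, because 2000 tags with a mean of 5 to 10 counts gave 384 to 492 calls with shuffled clones against 1009 calls. In those joint fits 2000 tags with a mean of at least 10 counts gave 50 to 78 against 554. Among the varieties, limma voom called about 2.0e+03 tags, a mean of 10 counts (added) gave 254, and leaving out each run gave 144 to 1483. Against the midparent, a mean of 20 counts (added) gave 380 calls, the family as 1 term (added) 43, and leaving out each parental plot 580 to 1029.

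Without the run as block the counts were 171 between the parents, about 2.1e+03 among the clones, 538 among the varieties and 1041 against the midparent, which moved none by over 1.5 times. Leaving out the libraries set apart (added) moved none of the counts for classes, parents, clones and midparent by over 1.5 times. A repeatability above 0.5 was then reached by 589 tags among the clones, against 562 with all libraries. Of 197 values of the 14 named tags, 2 of them named in 2 comparisons, under alternatives, 191 kept their direction and side of the threshold, and 6 lost the call with the direction kept: the 4 parental tags in the 6 libraries alone and the 2 tags below the midparent with the family as 1 term.

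Other groupings of the samples were fitted on seeded samples of tags. For the varieties against the clones, 1 of 100 splits, the real one, gave as many as 127 calls and the highest other 5. Most genotypes are clones of 1 family, so most other splits compared clones with clones. These splits show that the varieties differ from the family, and cannot decide on a difference between the ploidy classes. Chance can be excluded among the clones, with 1 of 50 shuffles at 533 calls and the highest other at 41, and among the varieties, with 1 of 99 at 65 and the highest other at 2. For the parents the 10 splits are too few for a share under 0.05, and the real one gave 208 calls, as did 1 of 10, and the highest other 0. For the midparent chance cannot be excluded, because 8 of 60 pairs of clones put in the place of the parents, the real pair included, gave at least its 30 calls, and the highest other gave 33. Not run were a fit without a count filter, tags matched to genes, and gene lists.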

Other observations

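The test reported in this part was chosen after the result was seen. Tags found in 1 parent only went through the family in groups. Among the tags in 30 to 70% of the clones, 133 of 07506-01 and 106 of 12120-03, average linkage on the absolute phi of their presence (at least 0.6) gave 12 and 10 groups of 3 or more tags, with 53 and 52 tags in them. In 200 shuffles of the clones for each tag no such group arose, and the highest phi was 0.515 and 0.538.

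Linkage on the chromosomes of the parent is a candidate explanation for these groups. Copying errors are not excluded for part of the 07506-01 tags, because tags 2 bases from a more abundant tag were kept. Tags 2 bases from the tag of 17134 CPM in 07506-01 entered the grouping, found in 53, 49 and 52 of 90 clones. Copies of 1 tag would occur in the same clones without linkage and add to the pairs. The groups without such tags were not tested. A clone of low depth or poor RNA would lose many tags at once and could give only pairs found in the same clones, whereas 2 homologous chromosomes also give pairs found in opposite clones. At an absolute phi of at least 0.6, 45 pairs of 07506-01 tags and 46 pairs of 12120-03 tags were found in opposite clones, beside 75 and 99 pairs in the same clones. The lowest phi was -0.907 and -0.929. With the libraries set apart left out, the pairs in opposite clones were 53 and 63. No map position was used here, so the groups stay a hypothesis.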
